A study of Escherichia coli str. K-12 substr. MG1655 with 48 samples.

How the data were processed

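The samples were 48 hybridisations of RNA from Escherichia coli K-12 strain MG1655, grown in continuous culture with or without air, before and after the addition of CORM-401, a manganese carbonyl compound that releases carbon monoxide. Per the labels, each 2-colour array held cDNA from a culture at 1 of 6 times after addition, from 2.5 min in doubling steps to 80 min, in either Cy3 or Cy5 and cDNA from the 0 min sample of the same culture in the opposite dye. There were 2 cultures per atmosphere and each culture and time was hybridised on 2 arrays with the dyes exchanged, which gave 12 groups of 4 arrays on 7 slides. No slide held both atmospheres. Per the labels' protocols, total RNA was extracted with Trizol and copied into cDNA with random primers and a Cy-labelled nucleotide. The dose of CORM-401 was not given in the sources used here.

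Per the file headers and the submitters' processing notes, spots were quantified with Agilent Feature Extraction 10.10.1.1. The deposited scanner files hold spot and local background intensity values on a linear scale, with no normalisation between the channels, and also a log10 ratio of Cy5 over Cy3 computed by the scanner software from its own background-subtracted and dye-normalised signals. The deposited table of the whole series holds log10 ratio values, which were found to equal the scanner software's log10 ratio with its sign turned on arrays that held the treated sample in Cy3. The largest difference from that ratio was 5e-06, so these values give CORM-401 over 0 min, and the 48 columns had medians between 0 and 0.0602. No further centring of these values was found. Of the columns of per-sample values, all were assigned to a sample through its own label.

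Ratios were computed again from the deposited intensity values. Each array held 15744 spots, of which 15188 were not controls and represented 4598 distinct probes. Median spot intensities were corrected with the local background medians by normexp with an offset of 50. The fixed plan had named the mean spot signal, which the files used here did not contain, and the median spot signal took its place. Ratios were normalised within each array by loess with a span of 0.3, in which control spots and spots that the scanner software marked as outliers had no weight. Outlier spots, 4.96% of the non-control spots, were left out, and 0 spots were saturated. Probes were named through locus tags and names in the files and a RefSeq list of genes of assembly ASM584v2. By locus tag 4074 matched, 281 by a name at the start of their systematic name and 117 by a synonym, while 126 matched no gene. The build behind the array design was not given in the sources used here, so no coordinates are printed. Spots of a probe and then probes of a gene were averaged. Of 4283 genes, 4261 had a probe well above background in either channel on at least 4 arrays and were tested.

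Every ratio was turned to CORM-401 over 0 min, and the 2 dye orientations of each culture and time were averaged, which left 24 values. limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8) fitted 12 group means and tested each against 0, with 12 residual and 2.45 prior degrees of freedom. The spread was pooled over both atmospheres because 2 cultures per group leave 1 degree of freedom each. Where a culture was left out, its remaining partner was assumed to vary like the other groups. Benjamini-Hochberg adjustment covered all genes and the 6 times together, separately for the aerobic response, the anaerobic response and the difference between them, with a threshold of 0.05. A gene counted as changed at any time if it passed at 1 or more of the 6 times. The adjustment covers tests of a gene at a time, so the share of false calls among such genes can exceed 0.05. The change from 10 to 80 min and the 0 min difference between atmospheres were adjusted over genes. For 0 min, single-channel log2 intensities after loess and Aquantile normalisation were averaged per RNA, which gave 28 RNAs in 14 groups. A gene that was well above background on none of the arrays of a group, in the channel of that RNA, has a bound in place of a ratio: the brighter group's mean against the mean of, per array, the higher of the lowest well-measured signal and the gene's own.

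Before the data were examined, 32 lists with 680 entries were fixed from knowledge of E. coli, together with the alternatives and the rule for naming genes. They were tested where at least 4 genes were measured, which was so for 31 lists and 655 genes. The manganese list had 3 measured genes. camera with a preset correlation of 0.01 compared each list with all other genes at each time, and was run again with an estimated correlation. The naming rule took the 10 highest and 10 lowest peak ratios per atmosphere among genes past the threshold with 1 sign on all 4 arrays, the 5 highest and 5 lowest of each other comparison, up to 4 members of each described list by peak size, and a fixed set of well-known genes whether changed or not. Symbols given without a value as members of a small count were named after their values were seen.

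The cultures carry the same number at every time because the same culture was sampled throughout, so their values pair over time. Over the 15 pairs of times, the correlation across genes between the culture differences was 0.21 to 0.838 in aerobic cultures and 0.563 to 0.907 in anaerobic cultures, with medians of 0.696 and 0.75, and the correlation within a culture estimated by limma was 0.527. All times of a culture also share its 0 min RNA, so no overlap between times was taken. The steps were tested on simulated ratios with 4261 genes of which 200 were changed at known sizes. Each changed gene was shifted alike at all 6 aerobic times, with a correlation within a culture set slightly under 0.527. In the data 12 of 369 aerobic genes passed at all 6 times and 178 at only 1. Neither the recovery of shorter changes nor the number of unchanged genes passing beside them was therefore tested. For the aerobic comparison, 89.5% of genes changed 2-fold and 98% of those changed 4-fold were recovered (179 and 196 genes). Beside them 88 and 101 unchanged genes passed at 1 or more times, and 69 and 68 with the culture as a block. In the simulated anaerobic cultures, where no gene was changed, 0 and 1 genes passed without the block. For the difference between atmospheres the recovered shares were 72% and 95% (144 and 190 genes). Beside these 74 and 96 unchanged genes passed, and 54 and 64 with the culture as a block. The number of cultures, 2 per group, limits the precision: the median standard error of a group mean was 0.18 on the log2 scale, and 0.26 for a difference between groups. Alternatives covered the background correction, the signals, the normalisation, the filter on dim probes, the averaging of probes, the culture and the slide as blocks, single dye orientations, left-out cultures, the pooled spread, the prior and the threshold. Most slides held arrays of 1 culture, so the slide as a block also takes up spread between cultures, and that fit used single arrays.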

Results

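Transcript levels were measured after CORM-401, a carbon monoxide-releasing manganese carbonyl, was added to continuous cultures of wild-type E. coli MG1655 in Evans medium, a defined medium for chemostats. The study asked how gene expression changes over time after the addition, in cells growing with air and in cells growing without it. Each of the 12 groups (6 times in each atmosphere) held 4 arrays from 2 cultures, and every array compared a sample after addition with the 0 min sample of the same culture. Median spot intensities ranged from 93.5 to 475 in the treated channel and from 69.5 to 301 in the 0 min channel, and 42.3% to 100% and 31.4% to 83.9% of spots in these channels were well above background. Log2 ratios from the 2 dye orientations of an RNA correlated across genes at 0.511 to 0.962 (median 0.88). The lowest value belonged to the first aerobic culture at 10 min. The 20 min array of that culture with the treated sample in Cy5 correlated at 0.786 with its own dye swap and at 0.828 with the 10 min array of the opposite dye. Ratios of the 2 cultures correlated across genes at 0.294 to 0.702 in aerobic and 0.0894 to 0.673 in anaerobic groups (genes are not independent replicates). On the 4 arrays with the 80 min RNA of the second cultures, 97.9% to 100% of spots were above background in the treated channel. Cultures without the compound were not analysed here, so the ratios compare times of treated cultures with their own starting point.

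**Figure D1:**
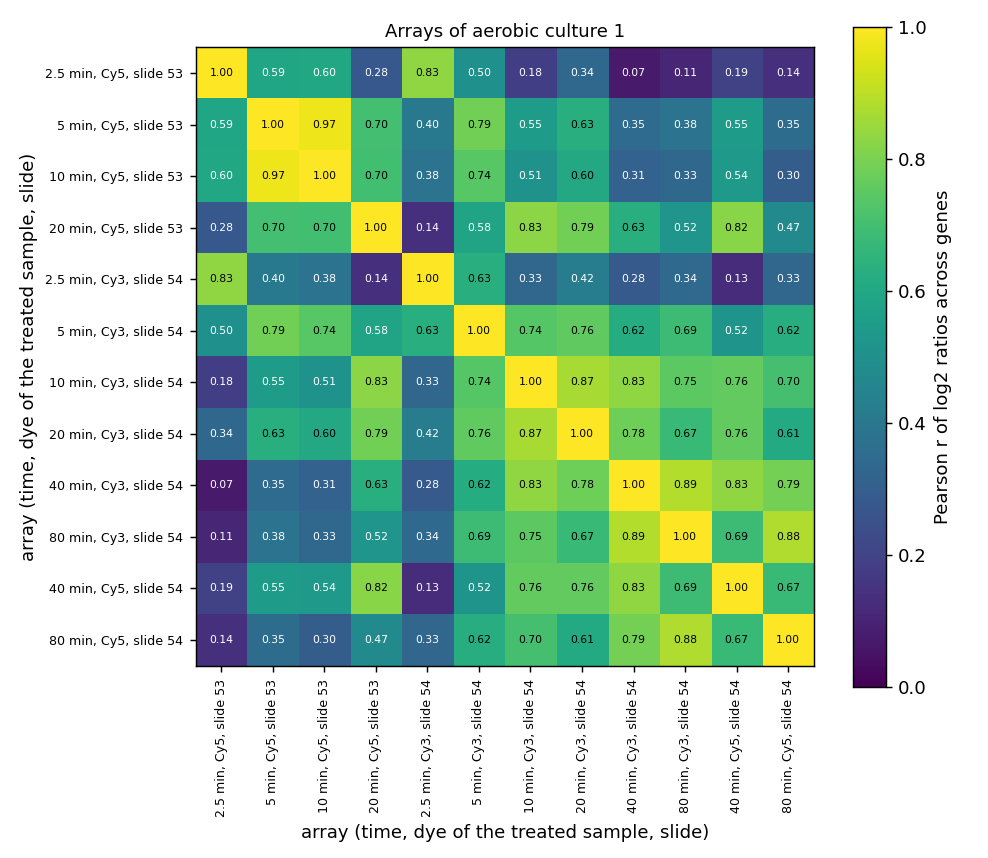
Pearson correlation across genes (colour scale) between the log2 ratios of the 12 arrays of the first aerobic culture, with time in minutes and the dye of the treated sample on both axes. The 10 min array with the treated sample in Cy5 correlated at 0.511 with the 10 min array of the opposite dye and at 0.742 with the 5 min array of the opposite dye.

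In aerobic cultures the highest ratio was that of spy, which encodes a periplasmic chaperone of the envelope stress response. It stood 8.50 ± 0.71 above 0 min at 40 min (log2 ratio ± SE, n = 2 cultures), a 362-fold rise (adjusted p = 1.59e-05). uhpT, the hexose phosphate transporter gene, rose by 6.58 ± 0.42 at 40 min, and cpxP, yebE and the membrane protease gene htpX rose by 3.96 ± 0.35, 3.80 ± 0.31 and 3.56 ± 0.40 at 10 min. znuA, which encodes the binding protein for zinc uptake, rose by 3.25 ± 0.30 at 40 min, and kdpA of the potassium transporter by 2.85 ± 0.70 at 20 min. Of the genes for acetate uptake and activation, actP fell by 4.18 ± 0.30, acs by 3.81 ± 0.34 and yjcH, from the same operon, by 3.61 ± 0.36, all at 40 min.

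Among the other leading genes, mdtA and mdtB of a multidrug efflux pump and the sensor kinase gene baeS were not well above background at 0 min. They rose at least 9.76-fold, 6.78-fold and 6.15-fold, with mdtA and mdtB at 20 min and baeS at 40 min (adjusted p = 0.00541, 0.000827 and 0.00591). The outer membrane porin gene ompF fell by 3.71 ± 0.79 at 20 min, and mglB, for the galactose binding protein, fell by 3.33 ± 0.56. The small RNA gene ryjA fell by 3.27 ± 0.30 at 80 min, and the curli subunit gene csgA fell by 2.89 ± 0.59 at 40 min. At 20 min aldA, fumA and cstA fell by 2.97 ± 0.30, 2.88 ± 0.22 and 2.69 ± 0.37. These 20 genes were chosen among those with 1 sign on all 4 arrays of their time. Without aerobic culture 1, 9 of them no longer passed (mdtA, mdtB, baeS, kdpA, ompF, mglB, aldA, csgA and cstA, with adjusted p up to 0.528), and without aerobic culture 2, 6 no longer passed (htpX, mdtA, baeS, kdpA, mglB and cstA, up to 0.47). ompF and csgA also did not pass without either anaerobic culture (up to 0.0593).

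**Figure D2:**
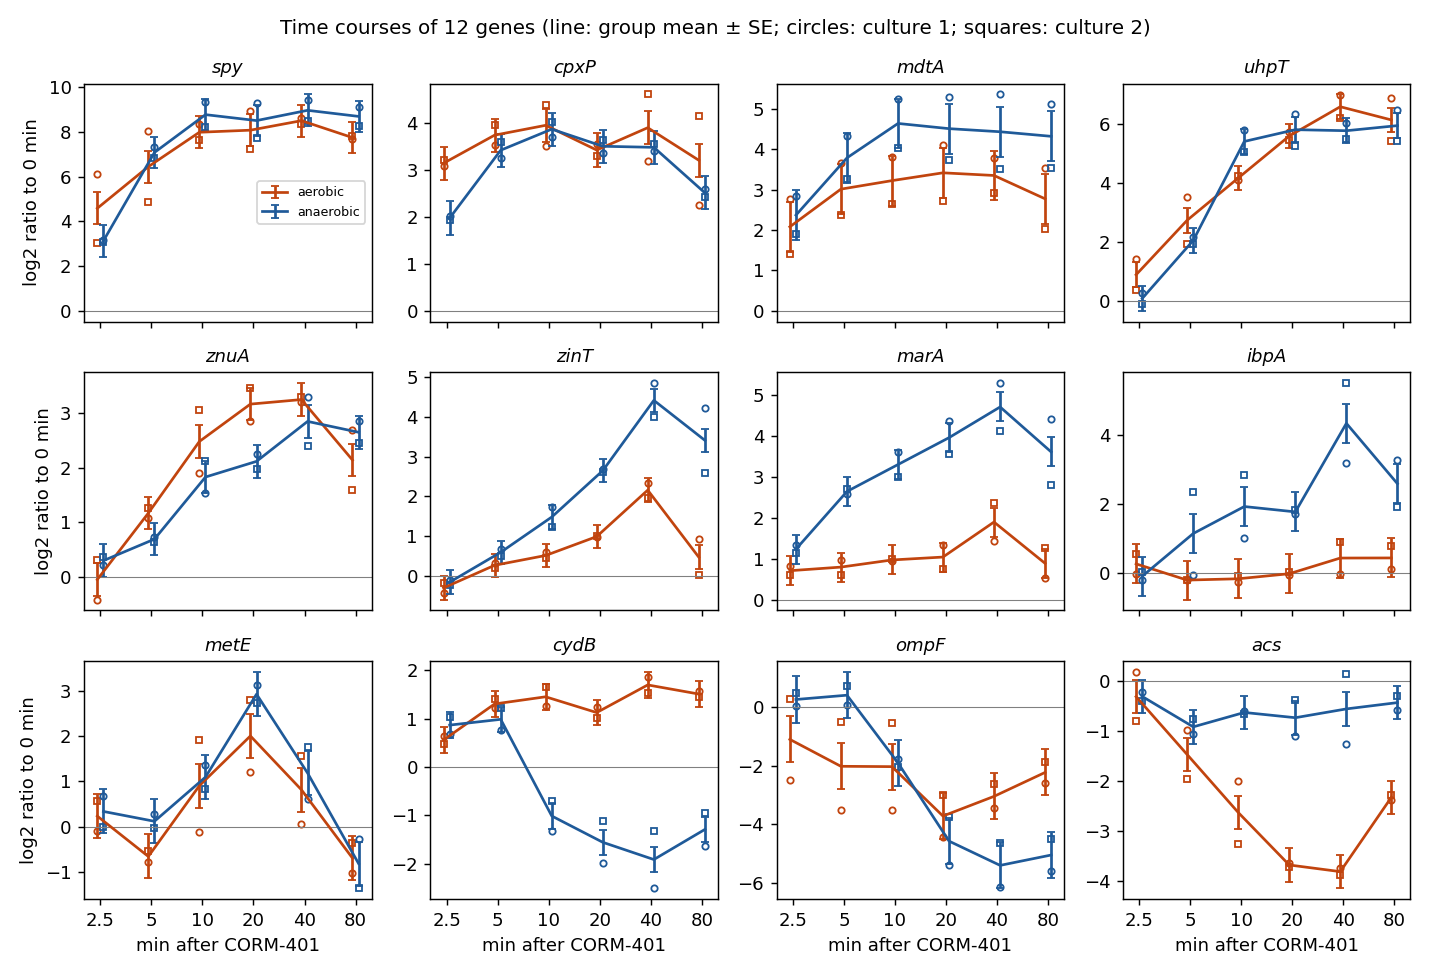
Log2 ratios to 0 min (vertical axes) of 12 genes against minutes after CORM-401 (horizontal axes, evenly spaced times), with lines and bars for group means ± SE and open symbols for the 2 cultures of each atmosphere. At 40 min spy reached 8.50 in aerobic and 8.96 in anaerobic cultures, whereas cydB stood at 1.70 and -1.91, and the aerobic ibpA ratios rest on a 0 min signal not well above background.

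Of 24 measured envelope stress genes 13 rose in aerobic cultures at 1 or more times (15 rose, adjusted over the list alone), including dsbA and ppiA, for periplasmic folding factors, and the cpxA, cpxR, baeS and baeR regulators. The list stood above other genes at each time (camera, adjusted p = 1.97e-13 at 10 min). With an estimated correlation the adjusted p = 0.0114 at 10 min, and the list no longer passed at 2.5 and 80 min (adjusted p = 0.0611 and 0.0594). Nucleotide synthesis genes rose in 18 of 29 cases (24 adjusted over the list alone) and none fell. Examples were the aspartate transcarbamoylase genes pyrI and pyrB, up by 2.57 ± 0.63 and 2.44 ± 0.55 at 40 min, and guaB and guaA of GMP synthesis, up by 2.21 ± 0.37 and 1.91 ± 0.39 at 20 min. That list gave a camera adjusted p = 1.52e-10 at 40 min, and an adjusted p = 0.0611 with an estimated correlation. carA and carB, which make carbamoyl phosphate, rose by 2.04 ± 0.43 and 1.88 ± 0.43 at 40 min and were the 2 of 14 arginine biosynthesis genes that changed (2 adjusted over the list alone). The arginine list lay below other genes at 2.5 min (median -0.73, camera adjusted p = 0.00155), with an adjusted p = 0.681 with an estimated correlation, and at 5 min (median -0.77, camera adjusted p = 0.0149, 0.774 with an estimated correlation).

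In the TCA cycle 13 of 16 genes fell in aerobic cultures (15 fell and 1 rose, adjusted over the list alone), with gltA, acnB and acnA at -1.65 ± 0.33, -1.77 ± 0.17 and -1.73 ± 0.42 (20, 20 and 40 min). The camera adjusted p at 20 min was 3.4e-21, and the adjusted p = 0.0121 with an estimated correlation. Of the gluconeogenesis and glyoxylate genes 5 of 11 fell (7 fell and 1 rose, adjusted over the list alone), among them pck at -1.67 ± 0.37 and aceA at -0.98 ± 0.17 at 20 min. At that time camera gave an adjusted p = 2.85e-08, and an adjusted p = 0.0114 with an estimated correlation. Among 19 NADH and succinate dehydrogenase genes 6 fell (7 adjusted over the list alone), with nuoF also higher at another time. sdhA and sdhB fell by 2.40 ± 0.40 and 1.99 ± 0.33 at 20 min, and sdhD, not well above background after treatment, fell at least 5.36-fold. The list lay below other genes at 20 min (camera adjusted p = 3.28e-10), with an adjusted p = 0.292 with an estimated correlation. Of 14 cytochrome oxidase genes 4 rose and 4 fell, with cyoB counted in both (7 and 5 adjusted over the list alone). cydA and cydB of the high-affinity bd oxidase rose by 1.75 ± 0.43 and 1.70 ± 0.26 at 40 min, while cyoD and cyoC of the bo oxidase fell by 1.77 ± 0.16 and 1.67 ± 0.29 at 20 min. That list's camera adjusted p = 5.43e-05 at 80 min went with an adjusted p = 0.184 with an estimated correlation.

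Of 40 iron acquisition genes 8 rose and efeU fell in aerobic cultures (15 and 1 adjusted over the list alone), among them exbD, feoB, entE and entC at 1.37 ± 0.31, 1.18 ± 0.17, 1.16 ± 0.21 and 0.96 ± 0.12 at 20 min. The list's camera adjusted p = 1.85e-10 at that time, and the adjusted p = 0.0611 with an estimated correlation. Of 20 zinc and copper genes zntA, zinT, znuA and copA rose (4 adjusted over the list alone), with zinT at 2.16 ± 0.29 and copA at 0.70 ± 0.16 at 40 min. Camera gave that list an adjusted p = 0.000671 at 40 min, with an adjusted p = 0.0821 with an estimated correlation. Of the manganese genes, mntH, for the uptake transporter, fell by 0.66 ± 0.12 at 40 min (adjusted p = 0.00597), and mntP, for the exporter, had a largest ratio of -0.47 ± 0.21 at 80 min (adjusted p = 0.316). htpX was the 1 of 24 heat shock genes that changed (1 adjusted over the list alone), and the ratio of ibpB, a small heat shock chaperone gene, was 0.40 ± 0.40 at 80 min. Its neighbour ibpA was not well above background at 0 min, and against the floor its largest ratio was 1.21-fold, also at 80 min (adjusted p = 0.884). As a list, the heat shock genes lay above other genes at 2.5 min (median 0.65, camera adjusted p = 3.8e-07), with an adjusted p = 0.517 with an estimated correlation.

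Of 30 RpoS-dependent genes 7 fell and osmB rose in aerobic cultures (11 and 1 adjusted over the list alone). glaH, yjbJ and yciE fell by 2.57 ± 0.49, 1.45 ± 0.30 and 1.19 ± 0.11, at 20, 40 and 40 min, and osmB rose by 1.12 ± 0.24 at 5 min. This list lay above other genes at 2.5 min and below them at 40 min (camera adjusted p = 1.57e-09 and 1.77e-10), with adjusted p = 0.272 and 0.25 with an estimated correlation. Methionine biosynthesis genes metB, metE, metF and metH rose and metK fell among 15 (4 rose and 2 fell, adjusted over the list alone), with metE at 2.00 ± 0.49 and metF at 1.46 ± 0.28 at 20 min. The adjusted p = 0.000222 by camera at 20 min became an adjusted p = 0.403 with an estimated correlation. At 5 min the list had lain below other genes (median -0.66, camera adjusted p = 1.23e-05, 0.272 with an estimated correlation). Curli genes csgA and csgB were the 2 of 19 biofilm genes that changed (3 fell, adjusted over the list alone), and csgB fell by 2.39 ± 0.46 at 80 min. Camera placed the biofilm list below other genes at 4 times, and at 0 times with an estimated correlation. Of 18 phosphate starvation genes phoH, ugpB, ugpC, ugpE and ugpQ fell (5 fell and 1 rose, adjusted over the list alone). ugpB fell by 1.75 ± 0.20 and ugpE by 1.08 ± 0.16 at 40 min, and the list's adjusted p = 0.000101 by camera at 5 min was an adjusted p = 0.0367 with an estimated correlation. pflB, for pyruvate formate-lyase, rose by 1.54 ± 0.18 at 20 min. nfsB rose by 1.09 ± 0.22 at 20 min and was with nfo the pair of 18 superoxide response genes that changed (1 adjusted over the list alone), whereas soxS stood at -0.38 ± 0.67 at 80 min (adjusted p = 0.939). The superoxide list lay above other genes by camera at 3 times, and at 0 times with an estimated correlation.

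In all, 369 of 4261 genes changed at 1 or more times in aerobic cultures by limma, 214 of them higher and 157 lower, with 2 counted in both directions. From 2.5 to 80 min the numbers higher were 16, 42, 91, 105, 121 and 103, and the numbers lower were 2, 35, 50, 93, 77 and 63. Part of the count over all times can be false, since 88 unchanged genes passed beside 179 changed ones in the 2-fold simulation. Without aerobic culture 1 or 2 the count of 369 became 123 or 107, without either anaerobic culture it was 802, and with the slide as a block it was 1325. The majority turned with the aerobic cultures fitted alone (332 higher and 477 lower). It also turned with only the arrays whose treated sample was in Cy5 (149 and 199) and with the culture as a block (235 and 249), whereas only Cy3 gave 238 higher and 107 lower. Leaving out an anaerobic culture changes no aerobic ratio and leaves the spread to the aerobic groups, so it gave that same fit. Every aerobic slide held arrays of 1 culture, so the slide terms also take up spread between cultures. Leaving out the 10 min array with low dye swap agreement, that and the 20 min array of the same slide, all of the slide, or the 80 min RNA of the second cultures gave 492, 508, 489 and 382 genes, alternatives chosen after seeing the data.

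In anaerobic cultures spy again had the highest ratio, 8.96 ± 0.71 at 40 min (499-fold, adjusted p = 4.17e-06), and uhpT rose by 5.94 ± 0.42 at 80 min. yebE, mdtA and htpX rose by 4.72 ± 0.31, 4.64 ± 0.62 and 3.92 ± 0.40 at 10 min. At 40 min marA, a regulator of multidrug resistance, rose by 4.70 ± 0.35, the periplasmic protease gene degP by 4.45 ± 0.78, the zinc protein gene zinT by 4.42 ± 0.29, ibpA by 4.34 ± 0.56 and frmR, the repressor of the formaldehyde detoxification operon, by 4.01 ± 0.41. ompF fell furthest, by 5.40 ± 0.79 at 40 min (adjusted p = 0.000607). The galactitol uptake and use genes gatB, gatC, gatA and gatZ fell by 4.23 ± 0.40, 3.81 ± 0.44, 3.75 ± 0.32 and 3.21 ± 0.31 at 40 min.

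The maltose genes lamB and malE were at -4.29 ± 0.86 at 40 min and -3.66 ± 0.49 at 80 min, both lower than at 0 min. tnaA, for tryptophanase, fell by 3.75 ± 0.69 and the small RNA gene cyaR by 3.11 ± 0.30 at 40 min, and gatD fell by 3.30 ± 0.37 at 20 min. These 20 genes were chosen by the same rule as in aerobic cultures. Among them the cultures lay furthest apart for tnaA, degP, ibpA and gatC, with an SD of 2.24, 1.65, 1.64 and 1.54 (n = 2). Without anaerobic culture 1 ompF and lamB no longer passed (adjusted p up to 0.125), lamB was also lost without anaerobic culture 2 (0.139), and degP and tnaA were lost without either aerobic culture (up to 0.0644), whose spread enters the pooled estimate.

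**Figure D3:**
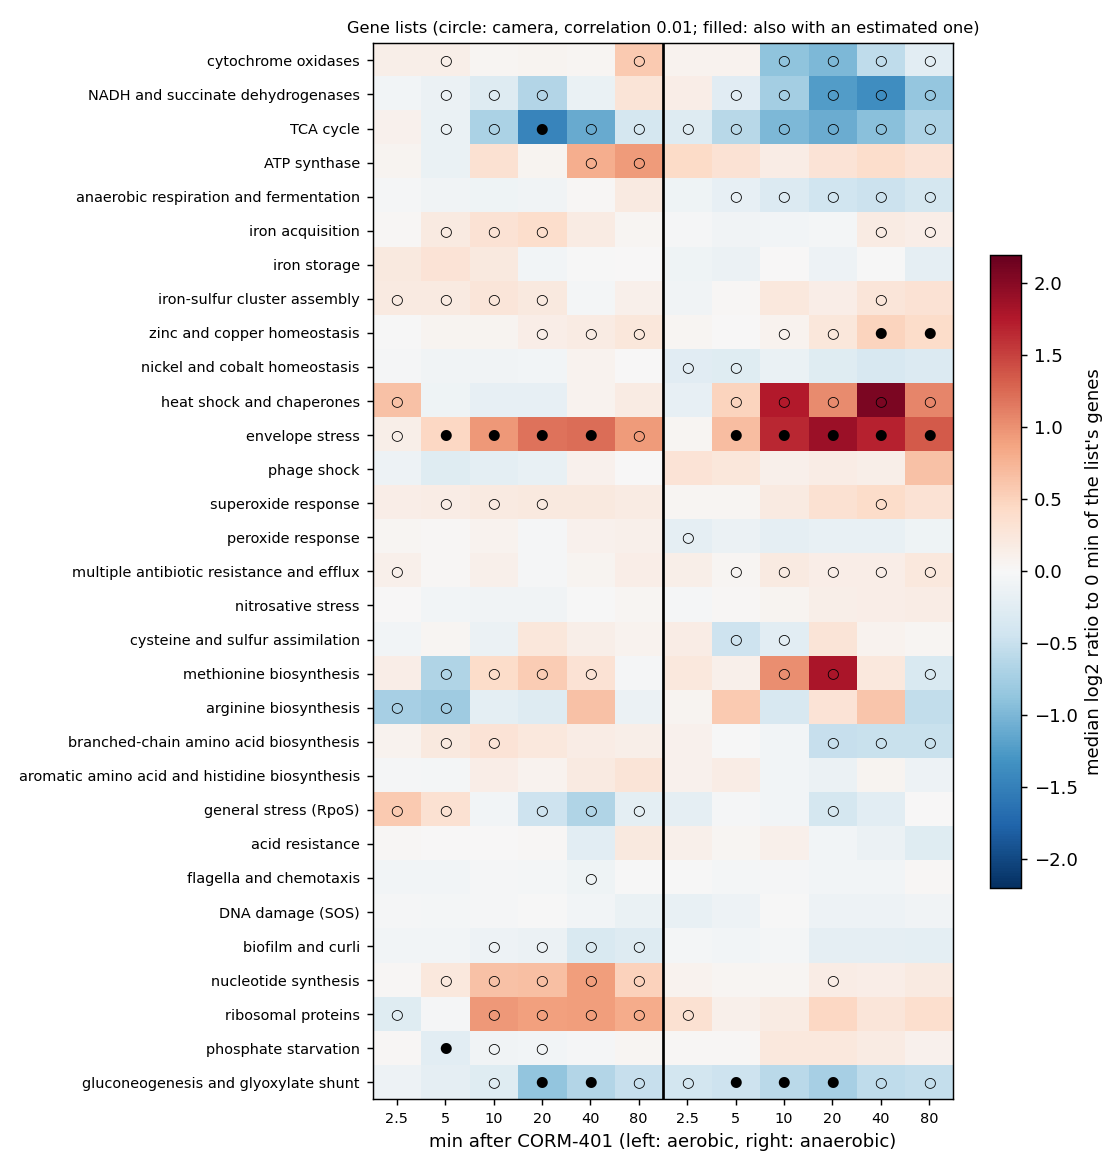
Median log2 ratio to 0 min (colour scale) of the 31 tested gene lists (vertical axis) at each time in minutes (horizontal axis, aerobic on the left and anaerobic on the right), with open circles for lists past camera's adjusted threshold and filled circles for those that also passed with an estimated correlation. Envelope stress is the list with filled circles at the most times, 4 in aerobic and 5 in anaerobic cultures.

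Of 24 envelope stress genes 15 rose in anaerobic cultures (15 adjusted over the list alone), cpxP among them at 3.88 ± 0.35 at 10 min, and camera gave an adjusted p = 2.53e-21 at 10 min and an adjusted p = 0.00493 with an estimated correlation. Of 24 heat shock and chaperone genes 12 rose (19 adjusted over the list alone), with ibpB at 3.75 ± 0.40 and htpG at 3.21 ± 0.85 at 40 min, where htpG stood at 1.91 and 4.51 in the 2 cultures (SD 1.84). The median of that list was 2.06 at 40 min (camera adjusted p = 2.55e-13), with an adjusted p = 0.196 with an estimated correlation. Of 25 multidrug resistance genes 7 rose (8 adjusted over the list alone). marR and marB rose by 3.91 ± 0.41 and 3.15 ± 0.29 and the outer membrane channel gene tolC by 1.05 ± 0.26 at 40 min, and the list's camera adjusted p = 0.00207 at 10 min went with an adjusted p = 0.0771 with an estimated correlation. Of 18 superoxide response genes nfo, nfsB, acrA, tolC and rimK rose (5 rose and 1 fell, adjusted over the list alone), and soxS itself stood at -1.59 ± 0.67 at 80 min (adjusted p = 0.221). At 40 min camera gave that list an adjusted p = 0.00158, and an adjusted p = 0.481 with an estimated correlation.

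Some metal genes rose without air. Of 20 zinc and copper genes 8 rose (9 adjusted over the list alone), including the copper exporter gene copA at 1.62 ± 0.16 and ykgM, for a zinc-free ribosomal protein paralog, at 3.18 ± 0.53 at 80 min, and znuA at 2.85 ± 0.30 at 40 min. The ykgM value came from 4.86 and 1.49 in the first and second culture (SD 2.39). Camera gave an adjusted p = 6.41e-07 at 40 min, and an adjusted p = 0.0284 with an estimated correlation. Of 40 iron acquisition genes 11 rose (11 adjusted over the list alone), such as exbD at 1.13 ± 0.31 and fhuA at 1.07 ± 0.23 at 40 min and feoB at 0.96 ± 0.17 at 2.5 min. Their camera adjusted p = 0.0099 at 40 min became an adjusted p = 0.512 with an estimated correlation. Among 5 iron storage genes ftnB rose by 1.74 ± 0.31 at 10 min and ftnA fell by 2.56 ± 0.24 at 80 min (1 and 1 adjusted over the list alone). mntH rose by 0.48 ± 0.12 at 80 min, and mntP had a largest ratio of -0.46 ± 0.21 at 2.5 min (adjusted p = 0.257).

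Methionine biosynthesis genes rose in 13 of 15 cases, with metQ also lower at another time (14 rose and 3 fell, adjusted over the list alone). At 20 min metB, metE, metF and metL stood at 3.27 ± 0.33, 2.92 ± 0.49, 2.78 ± 0.28 and 2.45 ± 0.40, and the list's camera adjusted p = 8.31e-14 went with an adjusted p = 0.0591 with an estimated correlation. At 80 min the list lay below other genes (median -0.34, camera adjusted p = 0.0364, 0.675 with an estimated correlation). Of 33 sulfur assimilation genes cysC, iaaA and gsiA rose and cysH, cysM and tcyP fell (3 and 2 adjusted over the list alone). cysM and cysH fell by 1.54 ± 0.21 and 1.34 ± 0.37 at 10 min, iaaA rose by 1.44 ± 0.31 at 20 min, and the adjusted p = 2.97e-08 by camera at 5 min, with the list below other genes, became an adjusted p = 0.121 with an estimated correlation. Branched-chain amino acid genes fell in 7 of 15 cases (7 adjusted over the list alone), with ilvC at -2.15 ± 0.22 and leuD at -0.96 ± 0.23 at 40 min and ilvB at -1.53 ± 0.33 at 20 min. The camera adjusted p = 1.65e-05 for that list at 80 min was an adjusted p = 0.0591 with an estimated correlation.

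Of 19 NADH and succinate dehydrogenase genes 12 fell in anaerobic cultures (18 adjusted over the list alone), including nuoA at -1.56 ± 0.41 at 40 min and sdhB at -1.79 ± 0.33 at 20 min. The list's median was -1.36 at 40 min (camera adjusted p = 2.55e-13), with an adjusted p = 0.169 with an estimated correlation. Among 14 cytochrome oxidase genes 8 fell, of which cydB and cydX were also higher at another time (5 rose and 10 fell, adjusted over the list alone). cydA and cydB fell by 1.77 ± 0.43 and 1.91 ± 0.26 at 40 min and cyoD by 1.48 ± 0.16 at 5 min. The camera adjusted p at 10 min was 1.19e-06, and the adjusted p = 0.0918 with an estimated correlation. Of 43 anaerobic respiration and fermentation genes 11 fell and fdnH rose (19 and 2 adjusted over the list alone). The nitrite reductase genes nrfB and nrfA fell by 1.70 ± 0.45 and 1.52 ± 0.35 and dmsB by 1.47 ± 0.27 at 40 min, when camera gave an adjusted p = 1.9e-08 and an adjusted p = 0.0887 with an estimated correlation. In the TCA cycle 9 of 16 genes fell and mqo rose (14 and 1 adjusted over the list alone), with gltA at -1.98 ± 0.33 at 20 min. The camera adjusted p = 4.7e-11 at 10 min became an adjusted p = 0.0591 with an estimated correlation. Of 11 gluconeogenesis genes aceA, aceB, pck and maeB fell (7 adjusted over the list alone), with pck at -1.82 ± 0.37 at 40 min, and the list's camera adjusted p = 7.52e-05 at 5 min was an adjusted p = 0.0424 with an estimated correlation. katG and ahpC, peroxide defence genes, fell by 2.03 ± 0.28 at 40 min and 0.85 ± 0.21 at 20 min. With mntH they were the 3 of 15 peroxide response genes that changed (3 adjusted over the list alone).

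In anaerobic cultures 642 of 4261 genes changed at 1 or more times by limma, 389 higher and 258 lower, with 5 in both directions. The numbers higher from 2.5 to 80 min were 28, 70, 153, 210, 223 and 217, and the numbers lower were 22, 31, 78, 167, 193 and 161. As for the aerobic count, part of the count over all times can be false. That more genes changed in anaerobic than in aerobic cultures (642 and 369) depended on the processing. Each atmosphere fitted alone gave 326 anaerobic and 802 aerobic genes, and scale normalisation 317 and 577. The scanner's processed signals gave 476 and 557, and the deposited log10 ratios 498 and 573. The anaerobic count stayed higher with median centring (390 and 217) and without background correction (607 and 472), among others. More genes were lower than higher without anaerobic culture 1 (612 higher and 686 lower), without anaerobic culture 2 (286 and 347) and with only probes above background in both channels of every array (85 and 127). The count of 642 became 1285 without anaerobic culture 1, 326 without either aerobic culture and 1993 with the slide as a block. Without the 80 min RNA of the second cultures, an alternative chosen after seeing the data, it was 584.

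**Figure D4:**
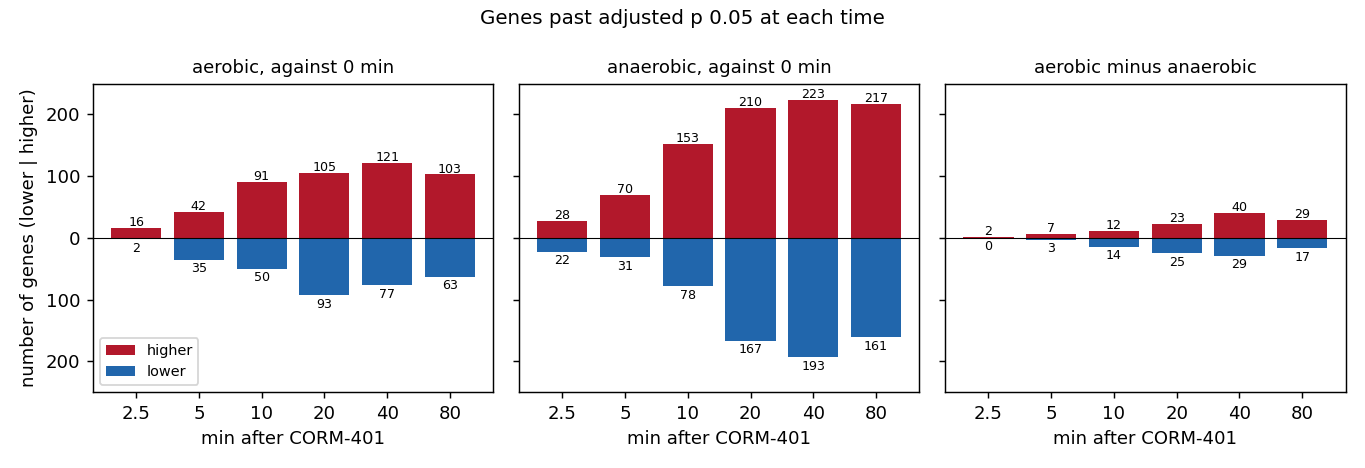
Number of genes past an adjusted p of 0.05 (vertical axis, higher above and lower below 0) at each time in minutes after CORM-401 (horizontal axis) for aerobic cultures, anaerobic cultures and the difference between them. The largest bars are at 40 min in anaerobic cultures, with 223 genes higher and 193 lower. Which atmosphere had more changed genes depended on the processing.

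The responses of the 2 atmospheres were compared directly, gene by gene and time by time. Among the bd oxidase genes, cydB differed by 3.61 ± 0.37 at 40 min (aerobic minus anaerobic, adjusted p = 0.000394), from 1.70 in aerobic and -1.91 in anaerobic cultures. The galactitol genes gatB, gatC and gatA differed by 4.04 ± 0.56, 3.90 ± 0.62 and 3.73 ± 0.45, with anaerobic ratios of -4.23, -3.81 and -3.75 and aerobic ratios of -0.19, 0.09 and -0.02. manZ of the mannose uptake system differed by 3.93 ± 0.43, from 0.98 in aerobic and -2.96 in anaerobic cultures. In the opposite direction the small heat shock gene ibpB differed by -3.73 ± 0.57 (adjusted p = 0.00627), having risen in anaerobic cultures. ibpA passed as well (adjusted p = 0.0346), but was not well above background at 0 min in aerobic cultures, so its difference has no exact size. The acetate genes actP, acs and yjcH differed by -3.33 ± 0.42, -3.25 ± 0.48 and -3.11 ± 0.51, having fallen in aerobic cultures, and all of these differences were at 40 min. In single-channel log2 signal, actP, acs and yjcH were higher in aerobic cultures by 4.03, 4.48 and 3.27 at 0 min and by 0.61, 1.18 and 0.25 at 40 min. Their anaerobic signals at 0 min were low, at 7.75, 7.76 and 7.24, though actP and acs were well above background on 23 of 24 arrays. mdtA and mdtB, not well above background at 0 min in aerobic cultures, stood at 7.465 and 7.293 there. The acetate genes thus had little room to fall without air, which limits what their differences in response show.

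By list, 6 of 14 cytochrome oxidase genes (cydA, cydB, cydX and 3 cyo genes) stood higher in aerobic than in anaerobic responses and none lower (9 adjusted over the list alone), with a camera adjusted p = 5.57e-09 at 80 min and an adjusted p = 0.0854 with an estimated correlation. Among 19 dehydrogenase genes nuoC, nuoE, nuoF and nuoG were higher (4 adjusted over the list alone), with a camera adjusted p = 6.72e-12 at 80 min and an adjusted p = 0.244 with an estimated correlation. Of the heat shock genes dnaJ, ibpA and ibpB were lower in the aerobic response (3 adjusted over the list alone), and the list's median difference was -1.57 at 40 min (camera adjusted p = 9.48e-12), with an adjusted p = 0.27 with an estimated correlation. At 2.5 min that list was higher in the aerobic response (median 0.65, camera adjusted p = 0.000293, 0.601 with an estimated correlation). marA and marB were lower in the aerobic response (1 higher and 3 lower, adjusted over the list alone). That list's camera adjusted p = 0.027 at 80 min was an adjusted p = 0.244 with an estimated correlation. Branched-chain genes ilvC and leuA were higher (7 adjusted over the list alone), and for this list an adjusted p = 2.26e-09 by camera at 80 min was an adjusted p = 0.0348 with an estimated correlation. None of 18 phosphate starvation genes differed by itself (3 lower, adjusted over the list alone), although the list lay lower in the aerobic response at 10 min (median -0.36, camera adjusted p = 1.03e-05), with an adjusted p = 0.0348 with an estimated correlation. purM, pyrC and pyrD were higher among 29 nucleotide genes (5 adjusted over the list alone), with a camera adjusted p = 2.38e-09 at 10 min and an adjusted p = 0.12 with an estimated correlation. Of the envelope stress genes cpxA alone was lower in the aerobic response (2 adjusted over the list alone). The list lay lower at 20 min (camera adjusted p = 0.0114), but turned to higher after scale normalisation between arrays (adjusted p = 0.0293), and its adjusted p = 0.328 with an estimated correlation.

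In total 100 of 4261 genes differed between atmospheres at 1 or more times, 59 with a higher and 41 with a lower aerobic response. Here too part of the count can be false, since 74 unchanged genes passed beside 144 changed ones in the 2-fold simulation. There each changed gene was shifted at all 6 times, whereas 0 of the 100 genes passed at all 6 and 45 at only 1. The 74 therefore gives no share of false genes among the 100. After scale normalisation between arrays 40 genes differed, and the share with a higher aerobic response went from 59% to 30%. That share was 44.8% with only Cy5, 69.4% with only Cy3, 80% with only probes above background in both channels of every array and 83.3% without aerobic culture 1. The count was 12 without aerobic culture 1, 0 by limma without aerobic culture 2 (1039 genes with an unadjusted p under 0.05), 418 without anaerobic culture 1, 279 without anaerobic culture 2 and 773 with the slide as a block. None of the 10 differences above passed without aerobic culture 1 (adjusted p 0.0675 to 0.611) or without aerobic culture 2 (0.085 to 0.288), gatC did not without anaerobic culture 1 (0.0519) and acs did not without anaerobic culture 2 (0.0718). Of the genes that rose in aerobic cultures 118 also rose in anaerobic cultures, against 19.5 for independent lists, and 61 fell in both against 9.51. A further 12 genes rose in aerobic and fell in anaerobic cultures (13 for independent lists), and 3 went the other way (14.3 for independent lists). A gene has 1 pooled spread for both atmospheres, so genes of small spread pass more easily in both and the counts for independent lists can be too low. The opposite directions share that spread and showed no excess. Genes that respond alike in both atmospheres lower those counts, so this does not show how much of the overlap the spread gives. Across genes, which are not independent replicates, the log2 ratios of the atmospheres correlated at 0.25 at 2.5 min and at most 0.612, at 20 min (Pearson), with 6 times compared.

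Whether early changes lasted was examined between 10 and 80 min. In anaerobic cultures the formaldehyde detoxification gene frmB rose further, by 1.93 ± 0.26 from 0.86 at 10 min (adjusted p = 0.0112), and nfeR, at 0.00 at 10 min, rose by 1.30 ± 0.25. cyoD came back by 1.44 ± 0.22, from -1.47 at 10 min to -0.03 at 80 min. The methionine genes metF and metB came down by log2 differences of -2.49 ± 0.40 and -2.43 ± 0.46, and cyaR, ftnB and ybdL differed by -2.44 ± 0.43, -2.28 ± 0.43 and -2.28 ± 0.37. In aerobic cultures putA, for proline dehydrogenase, was higher at 80 than at 10 min by 1.64 ± 0.25 (adjusted p = 0.0366). These were among 3 genes higher and 7 lower in anaerobic cultures and the only gene in aerobic cultures by limma, where 209 and 217 genes had an unadjusted p under 0.05. These counts and the SEs above come from a fit that did not pair the 2 times of a culture. With the culture as a block, 78 genes differed in aerobic cultures (44 higher, 34 lower) and 60 in anaerobic cultures (16 higher, 44 lower). The 78 and 60 included the 1 and 10 genes above. Without aerobic culture 1 or 2 the aerobic count was 0 (298 and 115 genes with an unadjusted p under 0.05) and without either anaerobic culture it was 34, while the anaerobic count was 1 without anaerobic culture 1, 3 without anaerobic culture 2 and 4 without either aerobic culture. Without the 80 min RNA of the second cultures, an alternative chosen after seeing the data, the counts were 0 (189 genes with an unadjusted p under 0.05) and 3, all 3 of them higher, and putA and 7 of the 8 named anaerobic genes no longer passed, all but frmB. putA was also lost without either aerobic culture. Of the named anaerobic genes, metF, metB and ybdL still passed without either aerobic culture, ftnB alone without anaerobic culture 1, and frmB and ftnB without anaerobic culture 2 (adjusted p up to 0.583 for the others).

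The atmospheres were also compared before the addition. In single-channel log2 signal at 0 min, acs and actP were higher in aerobic cultures by 4.48 ± 0.38 and 4.03 ± 0.42, and sgcQ, sgcX and sgcC of a putative sugar uptake operon by 4.70 ± 0.51, 4.52 ± 0.40 and 4.28 ± 0.60 (n = 2 cultures each). These sgc genes were well above background on 10, 18 and 13 of 24 anaerobic arrays. With signals under the floor raised to it, their differences were 4.655, 4.511 and 4.272. fnrS, a small RNA made under anaerobic conditions, had a difference of -6.14 ± 1.49 (adjusted p = 0.0114). The fnrS difference no longer passed without anaerobic culture 1 (adjusted p = 0.199) or 2 (adjusted p = 0.164). ansB, ynfG and dmsA, the last for dimethyl sulfoxide reductase, were not well above background in aerobic cultures and were at least 8.55-fold, 7.57-fold and 6.40-fold higher in anaerobic cultures. The hydrogenase gene hybO was well above background on 3 of 24 aerobic arrays, and with signals under the floor raised to it was at least 7.56-fold higher in anaerobic cultures. By limma 182 genes were higher in aerobic and 317 in anaerobic cultures, 499 of 4261 in all. The count was 279 without aerobic culture 2, 184 without anaerobic culture 1 and 912 from means per slide with the culture as a block, and slide and atmosphere cannot be told apart at 0 min.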

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

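The tests of a mislabelled sample, of one factor for every spot and of a common level were chosen after the results were seen; the tests of the slide and of the cultures for the 10 min array and the spread of the added signal were chosen after the patterns, with their outcomes written before they were run.

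At 40 min 69 genes had a response that differed between atmospheres by the test of the difference itself, 40 with a higher and 29 with a lower aerobic response. For the 5 highest and 5 lowest by the naming rule the values, aerobic minus anaerobic on the log2 scale, were 4.04 for gatB, 3.93 for manZ, 3.90 for gatC, 3.73 for gatA, 3.61 for cydB, -3.90 for ibpA, -3.73 for ibpB, -3.33 for actP, -3.25 for acs and -3.11 for yjcH. The value for ibpA has no exact size, since its aerobic 0 min signal was not well above background. Among 124 tested probes that matched no gene and entered no comparison, 9 changed in aerobic and 16 in anaerobic cultures at 1 or more times. Sets of 4 values, 1 per array of a group, were checked for the ratios of the leading genes at their time and for the shares of spots above background in each channel, and in 64 such sets no single value lay past Dixon's 95% critical value. This check cannot exclude a deviating culture, whose 2 dye swaps give like values that hide each other. The aerobic 80 min treated shares of 54.3%, 70.3%, 97.9% and 99.3% were not flagged. The leading genes were also chosen for 1 sign on all 4 arrays.

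At 40 min cydA and cydB, for the bd oxidase, stood above 0 min in aerobic and below it in anaerobic cultures. Without air cydB had first risen, by 0.98 ± 0.26 at 5 min (adjusted p = 0.0388 by limma), so for cydB the opposite directions belong to later times. For cydA no rise without air passed at any time. Movement to a common level from different starting levels is argued against. The mean absolute difference between atmospheres in single-channel log2 signal grew by 2.41 from 0 to 40 min. Aerobic minus anaerobic, cydA went from -0.65 to 2.77 and cydB from -0.42 to 3.12. The order of the mean signals turned, but the 0 min differences are given without a test, so the starting order is not established. By the same measure actP, acs and yjcH drew together, from 4.03, 4.48 and 3.27 at 0 min to 0.61, 1.18 and 0.25 at 40 min. For their difference in response a common level is thus not argued against. At 40 min they stood at 7.63, 8.36 and 7.03 in aerobic and at 7.02, 7.18 and 6.77 in anaerobic cultures. Most of these signals are low, so the background can limit how far apart the atmospheres could lie. cydB stood at 1.86 and 1.54 in the aerobic and at -2.51 and -1.32 in the anaerobic cultures, and its difference no longer passed without either aerobic culture. Slide and atmosphere cannot be told apart for the single-channel levels. The oxygen supply, the difference between atmospheres that the design names, stays among the open explanations and was not tested.

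The array of the first aerobic culture at 10 min with the treated sample in Cy5 departed from its dye swap. Its correlation across genes was 0.511 with the dye swap and 0.974 with the 5 min array of the same slide and dye. Against an effect shared by the arrays of slide 53 as the whole cause, the correlation with the 5 min array of the opposite dye still exceeded that with the 10 min array by 0.283 after the mean departure of the slide's 2.5 and 20 min arrays from their dye swaps was subtracted (0.24 and 0.302 with either alone). The label of the 20 min array is itself in doubt, so only the 0.24 from the 2.5 min array bears on this. Against a difference between cultures, the dye swap correlated less with the second culture at 5 min than at 10 min, by a difference of -0.0522 (-0.0628 and -0.0599 with each dye), whereas for the array itself that difference was 0.361. A mislabelled sample may be the cause, since before any correction the correlation with the 5 min array of the opposite dye exceeded that with the 10 min array by 0.231. The next array of the slide, at 20 min, correlated at 0.828 with the 10 min array of the opposite dye and at 0.786 with its own dye swap, so more than 1 label is in doubt. Beyond the difference between cultures no biological explanation was tested, because the 10 min array and its dye swap are labelled as RNA of 1 culture.

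In the second cultures of both atmospheres, the weakest probes at 80 min had raised signal in the treated channel. One factor for every spot, as more labelled material would give, is undecided: the 2nd percentile as a share of the median was at least 0.188 on these 4 arrays and at most 0.187 on the other 44, while dye swaps of an RNA differed by 0.0212. A signal added alike to every probe, as DNA carried along could give, is undecided too. Among genes dim at 0 min the ratio of the interquartile range to the median reached 0.688, but it was that low on 21 of the other 44 arrays. A difference in the response of these cultures at 80 min was not tested and stays open.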

How the results depend on the processing

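The alternatives that leave out doubtful arrays were chosen after the data were seen; the others were not. Of 69 named gene results, none reversed in 1573 values under the alternatives: 1405 stayed past the threshold and 168 did not. Part of this was fixed in advance. The leading genes of each atmosphere were picked for 1 sign on all arrays of their time. For them, leaving out a culture or using a single dye could not reverse a ratio. Aquantile normalisation gave the main gene counts and kept all 59 results it covered. A cut at a log2 ratio of 1 could remove none of the 69, picked for size. Only 27 of the 69 had probes above background in both channels of every array. Without aerobic culture 1, aerobic culture 2, anaerobic culture 1 and anaerobic culture 2, 27, 24, 13 and 11 of the 69 no longer passed. Gene counts moved far more. Leaving out a culture of 1 atmosphere changes no ratio of the other atmosphere, so the counts of the other moved through the pooled spread alone. The same holds for each atmosphere fitted alone. Except there and where fewer arrays or genes entered, the cause was not tested.

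For the aerobic response, 369 genes became 557 with the scanner's processed signals, 573 with the deposited log10 ratios, 217 with median centring, 577 with scale normalisation between arrays, 119 with only probes above background in both channels of every array (1077 genes tested), 192 with a log2 ratio of at least 1, 802 fitted alone and 1325 with the slide as a block. Under the first 2 of these the median of all genes at a time lay up to 0.204 and 0.184 from 0. For the anaerobic response, 642 genes became 390 with median centring, 317 with scale normalisation, 207 with the strict filter, 303 with a log2 ratio of at least 1, 326 fitted alone and 1993 with the slide as a block. For the difference, 100 genes became 45, 40, 50 and 773 with median centring, scale normalisation, the strict filter and the slide as a block. The counts with the slide as a block carry a limit, since most slides held 1 culture and their terms also take up spread between cultures. Leaving out 1 culture gave 107 to 802 genes for the aerobic response, 326 to 1285 for the anaerobic response and 0 to 418 for the difference.

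Between 10 and 80 min in aerobic cultures, the 1 gene became 7 with processed signals, 8 with the deposited ratios, 78 with the culture as a block, 2 with only Cy3, 34 fitted alone and 21 with the slide as a block. It became 0 with scale normalisation, the strict filter, only Cy5, trend and robust estimation and without the 80 min RNA of the second cultures (140, 58, 413, 206 and 189 genes by limma at an unadjusted p under 0.05). Without the 10 min Cy5 array, without that and the 20 min array, and without slide 53 it was 5, 5 and 5. In anaerobic cultures the 10 genes became 0 with processed signals and 0 with the deposited ratios (145 and 143 unadjusted), 1 with median centring, 2 with scale normalisation, 2 with the strict filter, 60 with the culture as a block, 4 with only Cy5, 5 with only Cy3, 4 fitted alone, 4 with trend and robust estimation, 80 with the slide as a block and 3 without the 80 min RNA of the second cultures. Leaving out 1 culture gave 0 to 34 genes in aerobic and 1 to 4 in anaerobic cultures.

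At 0 min, 499 genes became 291 with a log2 difference of at least 1, 150 with the strict filter, 297 with only the arrays whose treated sample was in Cy5, 912 from means per slide and culture with the culture as a block and 184 to 426 without 1 culture. Against 207 list and time calls by camera there were 123 with the strict filter, 23 with an estimated correlation and 104 by fry, which tests a list by itself. Of the 207, 106 of the 195 still testable were kept with the strict filter and 3 turned direction, 23 were kept with an estimated correlation and 98 by fry. Under the other signals and scalings 178 to 202 were kept, and 1 turned. Low signal limits what the ratios show, since 31.4% to 83.9% of spots were well above background in the 0 min channel and 42.3% to 100% in the treated channel.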

Other observations

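The values below add to those of the report, mostly for lists that it did not describe in the comparison concerned, and no explanation was tested for them. In aerobic cultures rpsA was the 1 of 52 ribosomal protein genes that rose (1 adjusted over the list alone), by 1.11 ± 0.20 at 20 min. The median of that list was 0.95 at 10 min (camera adjusted p = 4.18e-10), with an adjusted p = 0.585 with an estimated correlation, after -0.26 at 2.5 min, below other genes (camera adjusted p = 0.0014, 0.833 with an estimated correlation). marA, rob and mprA rose among 25 multidrug resistance genes (3 adjusted over the list alone), with marA at 1.89 ± 0.35 at 40 min. The list's camera adjusted p = 0.0302 at 2.5 min went with an adjusted p = 0.237 with an estimated correlation. iscX rose by 0.54 ± 0.12 at 10 min among 16 iron-sulfur cluster genes (1 adjusted over the list alone), and gadX rose by 0.98 ± 0.25 at 2.5 min among 19 acid resistance genes (0 adjusted over the list alone by limma, 7 with an unadjusted p under 0.05). As a list, the iron-sulfur cluster genes lay above other genes by camera at 4 times, and at 0 times with an estimated correlation. flgA fell by 0.65 ± 0.15 at 80 min among 45 flagellar genes (0 adjusted over the list alone by limma, 9 unadjusted). focA and pflB rose among 43 anaerobic respiration and fermentation genes, leuA among 15 branched-chain genes, ssuC among 33 sulfur assimilation genes and tyrB among 26 aromatic amino acid genes (1, 2, 1 and 0 higher, adjusted over the list alone).

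In anaerobic cultures the acid resistance genes gadC, hdeA, hdeB and hdeD fell (4 of 19 adjusted over the list alone), with hdeA at -1.65 ± 0.44 and hdeB at -1.61 ± 0.35 at 80 min. purA, purF, purK, guaA and guaB rose among 29 nucleotide genes, with guaB at 1.48 ± 0.37 at 20 min (0 adjusted over the list alone by limma, 16 unadjusted). That list's camera adjusted p = 0.0449 at 20 min was an adjusted p = 0.649 with an estimated correlation. pstB, pstS and psiE rose and phoH fell among 18 phosphate starvation genes (3 and 1 adjusted over the list alone), with pstS, for the phosphate binding protein, at 1.11 ± 0.28 at 20 min. hscA, fdx and iscX rose among 16 iron-sulfur cluster genes (4 adjusted over the list alone), with hscA at 0.81 ± 0.14 at 40 min, and the camera adjusted p = 0.0112 at that time was an adjusted p = 0.612 with an estimated correlation. aroB, tyrA and pheA rose and aroG and trpA fell among 26 aromatic amino acid genes (3 and 2 adjusted over the list alone), with trpA at -1.84 ± 0.39 at 80 min. osmB rose and osmY and yciE fell among 30 RpoS-dependent genes (0 adjusted over the list alone by limma, 10 unadjusted). The biofilm genes bhsA and bssS rose among 19 (2 adjusted over the list alone), bssS by 1.90 ± 0.39 at 10 min and bhsA, not well above background at 0 min, at least 3.5-fold at 40 min. polB and recX, not well above background at 0 min, rose at least 1.42-fold and 1.14-fold, and dinI and dinD fell among 24 DNA damage genes (2 and 1 adjusted over the list alone).

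By limma 0 genes changed in either atmosphere among 9 ATP synthase genes (3 aerobic with an unadjusted p under 0.05), 9 nickel and cobalt genes (2 aerobic and 4 anaerobic), 7 phage shock genes (1 anaerobic) and 11 nitrosative stress genes (1 aerobic and 3 anaerobic), and the same was so when adjusted over the list alone. As lists, the ATP synthase genes lay above other genes at 40 min in aerobic cultures (median 0.80, camera adjusted p = 0.0249, 0.753 with an estimated correlation) and the nickel and cobalt genes below them at 5 min in anaerobic cultures (median -0.27, camera adjusted p = 0.036, 0.219 with an estimated correlation). In aerobic cultures 0 genes changed among 5 iron storage and 24 DNA damage genes (2 and 7 unadjusted), and in anaerobic cultures 0 among 14 arginine, 45 flagellar and 52 ribosomal protein genes (1, 17 and 1 unadjusted). By camera the ribosomal protein list lay above other genes at 1 time in anaerobic cultures, and at 0 times with an estimated correlation. The difference between atmospheres passed for zinT, lower in the aerobic response, for katG higher and mntH lower, for metH higher and mmuM and mmuP lower, for entC and feoC higher, for ftnA higher, for napH, hybC and pflB higher, for aceA and lpd higher and fumA lower, and for yciE, bhsA and bssS lower. By camera 24 lists differed between atmospheres at 1 or more times, and 7 of them in opposite directions at different times: TCA cycle, heat shock, sulfur assimilation, RpoS-dependent, ribosomal protein, iron acquisition and iron-sulfur cluster genes. With an estimated correlation 2 of the 24 passed, branched-chain amino acid and phosphate starvation genes, and none of the 7 did.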
